A study of Mus musculus with 6 samples.

How the data were processed

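Bulk RNA-seq of mouse astrocytes was analysed in 6 samples in 2 groups: 3 samples of astrocytes from SCLC brain grafts (tumour libraries 1 to 3) and 3 of astrocytes from sham-injected brains (sham libraries 1 to 3). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, frozen cells went to a commercial sequencing provider, which extracted total RNA, prepared the libraries and sequenced them on an Illumina instrument. The library kit, its strandedness and the read length are not given in the sources used here.

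The deposited values are estimated counts per transcript. Per the submitters' processing notes, Salmon 0.8.2 and DESeq2 1.28.1 were used with the mm10 build, and per the file headers each table lists a transcript with its length, effective length, TPM and estimated number of reads, which are Salmon's columns. The TPM values were deposited by the authors for each transcript and sum to 1000000 in each library; they were used here only to weight effective lengths in 1 alternative. The deposited lengths and effective lengths are in bases. Between 7.2% and 8.9% of transcripts had an effective length above their length; whether bias correction was switched on is not given in the sources used here. Salmon divides reads that match several transcripts among them, so genes with near-identical copies, such as Gapdh, Pgk1, Ldha, Eno1, Aldoa, the Hspa1a and Hspa1b pair and the H2 genes, have less certain levels. Reads of overlapping or antisense genes cannot be separated without strand, and the index held 40 long noncoding transcripts, so that class of RNA was hardly measured.

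The files list 113116 transcripts, of which 112841 were matched by identifier without version to GENCODE M21 (GRCm38, the same assembly as mm10). Matched transcripts carried 99.947% to 99.958% of the reads of each library; the other 275 transcripts were left out. Estimated counts were summed per gene and rounded to whole numbers, giving 35127 genes, of which 14666 had a total of 0. Totals ranged from 22133723 to 25800897 reads, a ratio of 1.17, so depth was similar in all libraries. Gene coordinates are those of GENCODE M21.

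The main test was edgeR 4.0.16 (R 4.3.3): TMM normalisation, genes kept by filterByExpr (minimum count 10, minimum total 15), robust quasi-likelihood fit with group as the only term over all 6 samples, and Benjamini-Hochberg adjustment with a threshold of 0.05. Log2 fold changes are tumour over sham. Each SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F. The SEs thus restate the test and are not separate estimates. CPM values are scaled by TMM library sizes and given as mean ± SD over 3 libraries. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 27 lists, and again with the correlation estimated per list; fry was a further alternative. Beside each list stand its calls over all genes and those adjusted over the list alone. Counts by size used CPM with 0.5 added and a fold of 2. Similarity of libraries was measured by the root mean square log2 difference and by a chi-square per gene between the counts of each pair, over genes with at least 20 reads in the pair.

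The tests were tried on simulated data with the real means and library sizes of the tumour against sham comparison (14359 genes simulated, 200 of them changed). In edgeR, which tested 14207 of them, 73% of the genes changed 2-fold and 97% of those changed 4-fold were recovered, and 6.1% of calls were unchanged genes. For DESeq2 1.42.0 these values were 77%, 94% and 10.5% over 14359 genes, and for limma-voom 71%, 95% and 5.1% over 14207. Of 26 lists without a change camera called 0. The simulated genes varied independently, so this cannot show how often camera calls lists of correlated genes. The simulation also held no libraries that nearly coincide, unlike the real data.

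The genes named were fixed by a rule before the data were examined, as were the lists, the tests and most alternatives. The rule takes the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap and whose mean is at least 5 CPM, leaving out predicted gene models and mitochondrial and ribosomal protein genes. It adds up to 4 called members of each list with the smallest p, or the 2 most abundant members where none was called, and 16 genes chosen in advance, among them Gfap, Vim, Serpina3n, Lcn2, C3, Aldh1l1, Slc1a3, Aqp4, S100b, Reln, Vldlr, Lrp8, Dab1 and Epcam. Not all genes the rule takes are named. The reelin pathway and part of the neuronal survival list were included because the published topic of the study names them. The 27 lists cover mature astrocytes, reactive astrocytes (3 lists), immature astrocytes and radial glia, interferon-stimulated genes, antigen presentation, chemokines and cytokines, complement, neuronal survival factors, synaptogenic factors, the reelin pathway, extracellular matrix, transmitter and potassium handling, cholesterol synthesis, hypoxia and glycolysis, proliferation, immediate early and heat shock genes, microglia and macrophages, other leukocytes, neurons, oligodendrocytes, their precursors, endothelium, mural cells and fibroblasts, ependyma and choroid plexus, and neuroendocrine and epithelial markers of SCLC.

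Alternatives were DESeq2, DESeq2 size factors or upper quartile factors in edgeR, no filter, a filter of 1 CPM in all 3 libraries of a group, transcript length offsets, limma-voom with and without sample quality weights, the replicate number as a block, each library left out in turn, and glmTreat against a log2 fold change of 1. After the data had been seen, the sums of near libraries and the counts by size against part of the sham libraries were added. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.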

Results

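RNA of mouse astrocytes was sequenced in 6 libraries. The 3 tumour libraries came from astrocytes taken out of brains that carried a graft of small cell lung cancer (SCLC), a neuroendocrine carcinoma that often spreads to the brain. The 3 sham libraries came from astrocytes of brains given a sham injection. The comparison asks how astrocytes next to SCLC differ from control astrocytes. The totals were 24524764, 24859978 and 25800897 estimated reads in tumour libraries 1 to 3, and 22133723, 23328811 and 22212985 in sham libraries 1 to 3. How the astrocytes were purified, and which animals or cultures each library came from, is not given in the sources used here. The p-values therefore measure only the spread between these libraries, which may be technical.

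Tumour libraries 1 to 3 almost coincided, as did sham libraries 1 and 2, whereas sham library 3 stood apart. Between the 4 pairs of near libraries the root mean square log2 difference over the tested genes was 0.322 to 0.352. It was 0.734 to 0.749 between tumour and sham libraries, and 0.795 to 0.802 between sham 3 and sham 1 or 2. The counts of each near pair had a chi-square per degree of freedom of 2.88 to 3.68, which repeat libraries of one preparation can give as well as separate samples. All 6 libraries were kept as separate samples only because the labels list them so. Sham 3 also differed in the share of reads on mitochondrial genes, 4.2% against 6.66% and 6.2% in sham 1 and 2, while the tumour libraries had 4.05% to 4.23%.

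**Figure D1:**
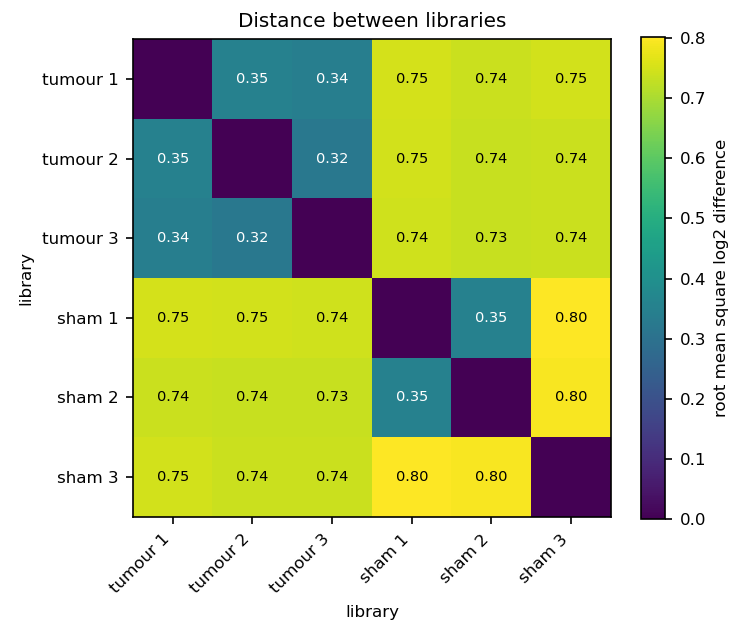
Root mean square log2 difference in counts per 1000000 reads (CPM) between each pair of libraries over the tested genes, shown as colour and number (both axes, the 6 libraries). The 3 tumour libraries lie within 0.352 of each other and sham 1 and 2 lie 0.351 apart, whereas sham 3 lies 0.802 and 0.795 from them.

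The tumour libraries had much higher levels of genes of the hypoxia response and of glycolysis. Tumour cells in the samples or conditions of a single preparation could also raise these genes, as set out in the closing section. Ndufa4l2, a mitochondrial protein gene induced by low oxygen, stood at 35.4 ± 1.09 CPM (SD, n = 3) in the tumour libraries and at 0.175 ± 0.0479 in the sham libraries, a log2 fold change of 7.62 (SE 0.16, edgeR adjusted p = 1.85e-05). Its sham values of 0.22, 0.125 and 0.181 CPM lie near those of 3 reads (0.125 to 0.136 CPM). The size of this fold is therefore uncertain, and its SE does not show that counting error. Slc16a3, the lactate exporter MCT4, rose from 2.11 ± 0.694 to 87.6 ± 0.937 CPM, and Car9, carbonic anhydrase IX, from 1.98 ± 1.31 to 65.5 ± 2.61 CPM. Among the genes that fell were the cholesterol synthesis gene Idi1, from 207 ± 126 to 55.3 ± 1.34 CPM, and Gjb6, which encodes the astrocyte gap junction protein connexin 30, from 17.9 ± 9.17 to 3.18 ± 0.218 CPM.

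Over 14359 tested genes, 1506 were higher and 1492 lower in the tumour libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 431 and 176 of them by 2-fold or more. In all 2998 of these genes the 3 tumour values lay on one side of the 3 sham values, which held for 44.1% of the tested genes. Chance gives 10% for 6 independent libraries and far more where near libraries are repeats, so this share is no evidence by itself. By size alone, 204 genes were at least 2-fold higher in each tumour library than in every sham library and 29 were at least 2-fold lower. Against sham 1 and 2 only these counts were 534 and 170, and against sham 3 only they were 699 and 196. By the same rule sham 3 alone stood above all other libraries in 86 genes and below them in 275, and sham 1 and 2 together in 94 and 228. The tumour libraries thus stood above all others in more genes than either sham set, but below them in fewer. These sets differ in their number of libraries, so the rule is not equally strict for each. The count of calls moved with each library left out: 536 to 542 genes were higher and 355 to 383 lower without 1 of the tumour libraries, 850 and 758 without sham 1, 824 and 693 without sham 2, and 4250 and 4179 without sham 3. That last fit tested 14618 genes and kept only sham 1 and 2, which almost coincided. Most genes were called in it, so a call made only without sham 3 says little about a gene or list. With the near libraries summed, so that 1 tumour value stood against 2 sham values, edgeR called 0 genes (538 at an unadjusted p below 0.05), limma-voom called 0 (688 at an unadjusted p below 0.05), and DESeq2 called 78 higher and 10 lower.

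The other large rises were Ak4 (adenylate kinase 4) with a log2 fold change of 4.66, Ankrd37 with 4.56, Galnt15 with 4.16, the pseudokinase gene Trib3 with 3.77, Nptx1 (neuronal pentraxin 1) with 3.56, Cdh3 (P-cadherin) with 3.45 and Car12 (carbonic anhydrase XII) with 3.34. The SEs of these changes were between 0.14 and 0.59, and the largest was that of Cdh3, whose adjusted p of 0.0111 passed the threshold only with all 3 tumour libraries in the fit. The largest falls were those of Aspa, which encodes the enzyme that splits N-acetylaspartate (log2 fold change -2.69, SE 0.65), Gjb6 (-2.49, SE 0.45), Lrrc4 (-2.18, SE 0.24), Idi1 (-1.90, SE 0.40), Enpep (-1.89, SE 0.34), Tspan13 (-1.88, SE 0.21), Mvd (-1.80, SE 0.49), Tmem158 (-1.77, SE 0.24), Gxylt2 (-1.62, SE 0.09) and St8sia2 (-1.60, SE 0.36). Sham 3 lay between the other sham libraries and the tumour libraries for Aspa, at 3.13 CPM against 19.3 and 17.5 in sham 1 and 2 and 1.74 to 2.34 in the tumour libraries. For Gjb6 it stood at 7.26 CPM against 23.3 and 23 in sham 1 and 2. For Idi1 and Mvd sham 3 lay farthest from the tumour libraries, at 352 CPM of Idi1 against 139 and 129 in sham 1 and 2. Of the 10 largest rises 9 stayed past the threshold whichever library was left out. Of the 10 largest falls 4 did, namely Lrrc4, Tspan13, Tmem158 and Gxylt2. The calls of Aspa, St8sia2, Mvd and Gjb6 were also lost under limma-voom. That of Aspa, kept in 6 of 19 alternatives, was lost as well without a filter, with transcript length offsets and with the replicate block. Without sham 3 the log2 fold changes were 5.72 for Car9, 4.60 for Cdh3, -1.28 for Idi1 and -0.99 for Mvd, and with transcript length offsets that of Car9 was 4.22. Among the smaller changes, the calls of Aldh1l1, Kcnj10, Cd14, Ggta1, Irf7, Irgm1 and Ccl2 ended without any 1 library other than sham 3. Those of Slc10a6, Slc6a9, Hspa1a, Serping1, Mdk, H2-T23, Lama2, Slc4a4, Cbs, Pdgfra, Kcnj16, Ncan, H2-D1, Psmb10, Mcm3, Thbs3, Notch1, Nes, Egfr, Hmgcs1, Fabp7, Dhcr7, Nsdhl and Syn1 ended without at least 1 of the tumour libraries. For genes named after their values were seen, leaving out libraries was not analysed here.

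The list of hypoxia and glycolysis genes rose almost in full. Of its 20 members, all tested, 18 were higher and 0 lower, and 20 were higher when adjusted over the list alone. The median log2 fold change was 1.71 (camera adjusted p = 8.34e-18 over 27 lists, and adjusted p = 0.0165 with an estimated correlation). Vegfa, the gene of the angiogenic factor VEGF-A, rose 6.98-fold to 423 ± 8.57 CPM (SD, n = 3), and the hexokinase gene Hk2 6.03-fold to 122 ± 3.21 CPM. The mitophagy receptor gene Bnip3 rose 5.87-fold to 427 ± 7.65 CPM. Pdk1, whose product holds pyruvate back from oxidation in the mitochondria, rose 4.19-fold to 123 ± 0.978 CPM. Members named after their values were seen include the glucose transporter gene Slc2a1, 7.17-fold higher, and the oxygen sensor gene Egln3, 7.37-fold higher. Ndrg1 (log2 fold change 0.81, adjusted p = 0.0727) and Higd1a (0.54, adjusted p = 0.122) were the 2 members not called over all genes. Over this list sham 3 had a median log2 difference of -0.10 from the mean of sham 1 and 2. Gapdh, Pgk1, Ldha, Eno1 and Aldoa have many near-identical copies in the genome, so their levels are less certain.

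**Figure D2:**
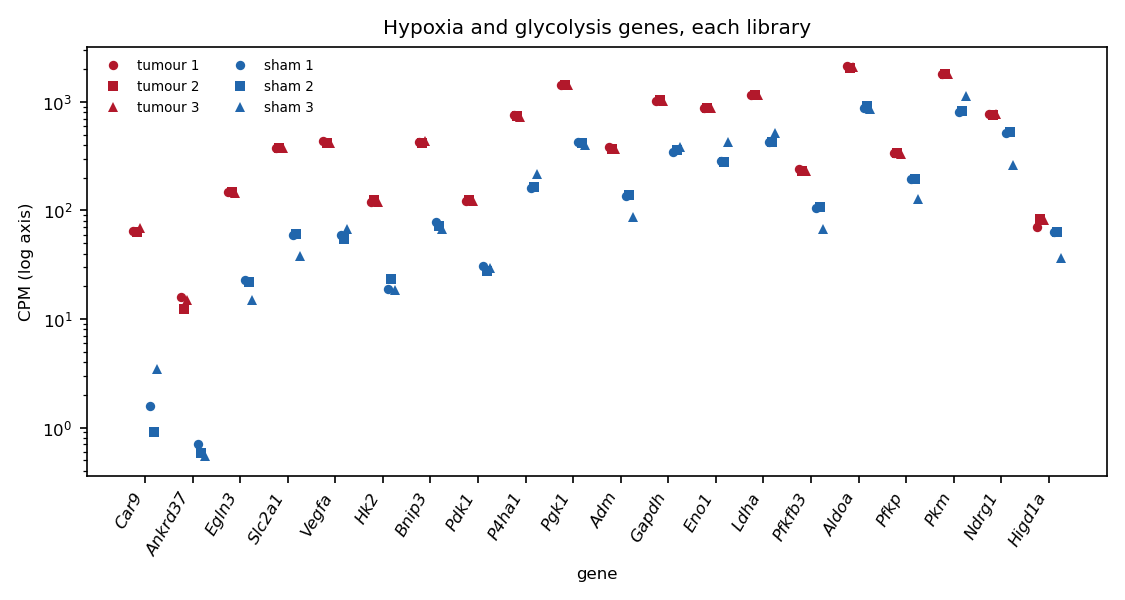
CPM (log axis) of the 20 hypoxia and glycolysis genes in each of the 6 libraries, ordered by log2 fold change; each point is 1 library. For all 20 genes the 3 tumour points lie above the 3 sham points, from Car9 (65.5 against 1.98 CPM on average) to Higd1a (78.9 against 54.3 CPM).

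Secreted factors known to support neurons were the other list that camera placed higher in the tumour libraries. Of 22 tested members 6 rose and 0 fell over all genes, and 9 rose and 3 fell when adjusted over the list alone. The median log2 fold change was 0.27 (camera adjusted p = 0.00984), a call that was lost with an estimated correlation (adjusted p = 0.309) and without sham 3 (adjusted p = 0.0544). Among the members, Vegfa, shared with the hypoxia list, rose from 60.6 ± 6.8 to 423 ± 8.57 CPM (log2 fold change 2.80, SE 0.10, edgeR adjusted p = 7.75e-05). It lies on chromosome 17 from 46016993 to 46032369 in the mm10 build. Hbegf (heparin-binding EGF-like growth factor; 1.78, SE 0.07) and Mdk (midkine; 0.83, SE 0.13) rose as well. Members that rose and were named after their values were seen include Serpinf1 (0.36) and Gdnf (1.03, at 1.78 CPM in the tumour libraries). Part of this list was chosen because of the published topic of the study, so its rise is not independent evidence.

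In the reelin pathway, which guides neuronal migration and was listed for the same reason, 1 of 9 members rose and 0 fell, also when adjusted over the list alone. That member was Vldlr, which encodes a reelin receptor, at 154 ± 3.06 CPM in the tumour libraries and 32.2 ± 10.7 CPM in the sham libraries (log2 fold change 2.26, SE 0.22, edgeR adjusted p = 0.00194). Vldlr lies on chromosome 19 from 27216484 to 27254231 in mm10. Reln itself was low in both groups, at 0.837 and 0.958 CPM. The other receptor gene Lrp8 had a log2 fold change of -0.21 (SE 0.12, adjusted p = 0.261) and the adaptor gene Dab1 one of 0.22 (SE 0.28, adjusted p = 0.613). The list as a set was not called (camera adjusted p = 0.911).

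**Figure D3:**
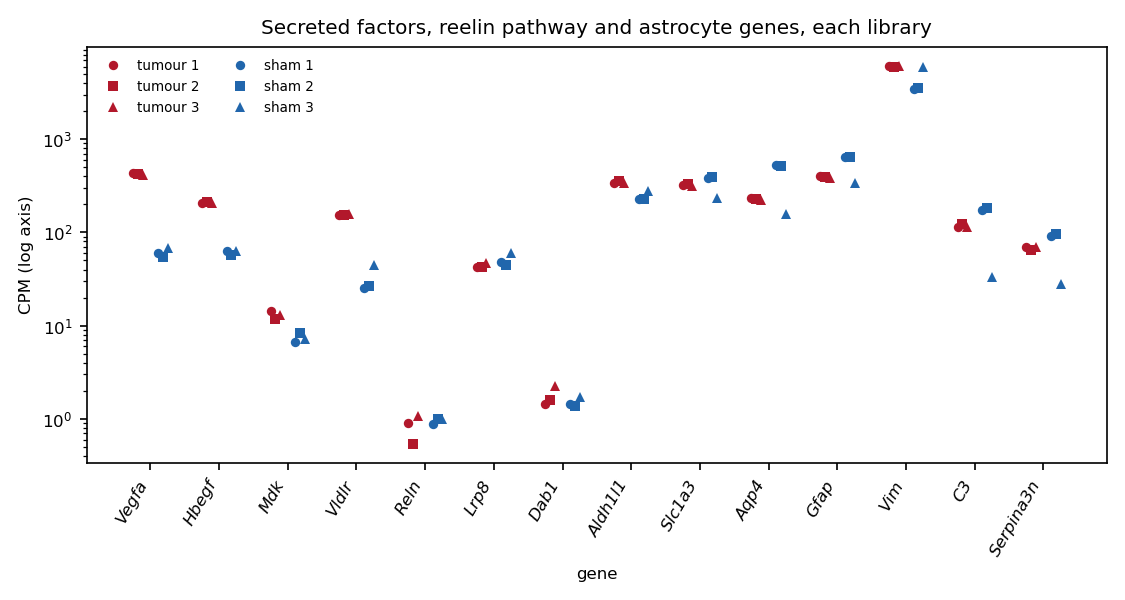
CPM (log axis) of 14 genes of secreted factors, the reelin pathway and astrocytes in each of the 6 libraries; each point is 1 library. Vegfa (423 against 60.6 CPM on average), Hbegf and Vldlr separate the groups, whereas for Aqp4, Gfap, C3 and Serpina3n sham 3 (triangles) lies below both the other sham libraries and the tumour libraries.

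Genes of mature astrocytes did not move as a set (24 tested, 4 higher and 3 lower, the same counts when adjusted over the list alone; camera adjusted p = 0.802). Among those that rose were the bicarbonate transporter gene Slc4a4 (log2 fold change 0.66, SE 0.11), Cbs (0.63, SE 0.11) and Aldh1l1 (0.48, SE 0.10), each of which lost its call without at least 1 of the tumour libraries. Gjb6, the potassium channel gene Kcnj10 (-0.65, SE 0.15) and Gja1 (connexin 43; -0.94), the last named after its value was seen, fell. The glutamate transporter gene Slc1a3 had 322 ± 9.41 CPM in the tumour and 337 ± 89.5 CPM in the sham libraries. The water channel gene Aqp4 had 229 ± 5.76 and 401 ± 210 CPM (adjusted p = 0.220), with 159 CPM in sham 3 and 535 and 510 CPM in sham 1 and 2. S100b had 7.62 ± 1.62 and 13.2 ± 5.84 CPM (adjusted p = 0.174). Without sham 3, where most tested genes were called, the fit called Slc1a3 (-0.27), Aqp4 (-1.19) and S100b (-1.11) lower. Slc1a3 had 0.02 and 0.06 without sham 1 or 2. Over the list, sham 3 was lower than the mean of sham 1 and 2 by a median log2 difference of -0.79, and without sham 3 the list was called lower in the tumour libraries (median log2 fold change -0.25, camera adjusted p = 0.0466).

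Calls among reactive astrocyte genes are to be read beside the 20.9% of all tested genes that were called. Of 13 genes raised after several kinds of injury 1 rose, the heat shock protein gene Hspb1, from 216 ± 23.8 to 500 ± 16.8 CPM (camera adjusted p = 0.056 for the list). Gfap, the intermediate filament gene commonly used as a marker of reactivity, had 392 ± 9.17 CPM in the tumour and 546 ± 176 CPM in the sham libraries (log2 fold change -0.48, SE 0.24, edgeR adjusted p = 0.211). Vim had 6070 ± 58.4 and 4290 ± 1380 CPM (adjusted p = 0.186), Lcn2 8.28 ± 0.517 and 5.63 ± 1.40 CPM (adjusted p = 0.0955), and Serpina3n 68.4 ± 2.52 and 71.5 ± 38.1 CPM (adjusted p = 0.929). Of 12 tested genes raised by lipopolysaccharide 4 rose, H2-T23 (0.81), Serping1 (0.86), H2-D1 (0.50) and Ggta1 (0.46), while C3 had 118 ± 5.19 and 129 ± 82.9 CPM (adjusted p = 0.887; camera adjusted p = 0.0674 for the list). Of 13 genes raised by ischaemia 2 rose, Slc10a6 and Cd14, both below 6 CPM (camera adjusted p = 0.132). When adjusted over the list alone these counts were 1, 4 and 3 higher. The injury list was called higher under fry (adjusted p = 0.00316), without a filter on low counts (camera adjusted p = 0.022) and with the replicate number as a block (0.0488). With an estimated correlation it was not called (camera adjusted p = 0.442). Its median log2 difference of the tumour libraries was 0.64 from sham 1 and 2 but 0.04 from sham 3. Without sham 3 the injury and ischaemia lists were called higher (camera adjusted p = 0.0121 for both), and without sham 1 or sham 2 the lipopolysaccharide list was (0.0422 and 0.0394). Without sham 3, where most tested genes were called, the fit also called Gfap (-0.73), Serpina3n (-0.45) and C3 (-0.59) lower and Vim (0.79) and Lcn2 (0.76) higher. Without sham 1 or 2 these 5 were not called, and Serpina3n (0.14 and 0.20) and C3 (0.13 and 0.19) had the other sign. Vim in sham 3, at 5890 CPM, was near the tumour level, whereas sham 1 and 2 had 3440 and 3550 CPM.

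Genes of radial glia and immature astrocytes included 4 that fell and 1 that rose among 19 tested, the same when adjusted over the list alone (camera adjusted p = 0.249). The gene that rose, named after its value was seen, was Sox4 (0.67). The 4 that fell were Nes (nestin; -1.01, SE 0.23), Fabp7 (-1.28, SE 0.26), Egfr (-1.06, SE 0.20) and Notch1 (-0.69, SE 0.11). Sham 3 had the highest Nes and Fabp7, at 98.5 and 139 CPM, and the lowest sham level of Egfr, at 289 CPM. Without sham 3 this list was called lower (camera adjusted p = 0.0418). Among genes of transmitter and potassium handling 3 of 15 rose, Grm3 (1.53), the glycine transporter gene Slc6a9 (1.44) and Kcnj16 (0.62), and 1 fell, Kcnj10 (camera adjusted p = 0.802, the same counts when adjusted over the list alone).

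Inflammatory lists held changes in both directions. Of 28 interferon-stimulated genes 2 rose, Ifi44 (0.83, SE 0.09) and Irf7 (0.45, SE 0.09), and 2 fell, among them Irgm1 (-0.36, SE 0.07), with a camera adjusted p of 0.912. Among 12 antigen presentation genes H2-T23 and H2-D1 rose and the immunoproteasome gene Psmb10 fell (-0.43, SE 0.10; camera adjusted p = 0.971). Of 14 tested chemokine and cytokine genes 3 fell and 0 rose, namely Cxcl12 (-0.69, SE 0.08), Il18 (-1, SE 0.14) and Ccl2 (-1.52, SE 0.41, at 1.6 CPM in the sham libraries), and the set was not called (camera adjusted p = 0.249). Of 12 complement genes C2 (0.94, SE 0.09) and Serping1 (0.86, SE 0.18) rose (camera adjusted p = 0.112; adjusted p = 0.0422 without sham 1 and 0.0394 without sham 2). For these 4 lists the counts were unchanged when adjusted over the list alone.

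Of 22 extracellular matrix genes 5 rose and 1 fell, the same when adjusted over the list alone (camera adjusted p = 0.0674). Fn1, the gene of fibronectin, rose 2.93-fold to 3200 ± 93.1 CPM (log2 fold change 1.55, SE 0.15), the collagen cross-linking enzyme gene Lox rose 2.04-fold to 2510 ± 27.8 CPM, and Lama2 and Ncan rose 1.60- and 1.45-fold. Spp1 (osteopontin; 1.40) rose and Mmp14 (-0.46) fell, both named after their values were seen. Sham 3 was above sham 1 and 2 over this list by a median log2 difference of 0.58, and without it the list was called higher (camera adjusted p = 0.000454). With all 6 libraries and an estimated correlation the list was far from called (camera adjusted p = 0.972). Among 17 tested factors that act on synapses 3 rose and 4 fell (3 and 5 when adjusted over the list alone), with Thbs4 (1.37, SE 0.15) and Megf10 (0.82, SE 0.06) higher and Thbs3 (-0.62, SE 0.10) and Chrdl1 (-0.62, SE 0.09) lower (camera adjusted p = 0.912).

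Genes of cholesterol synthesis fell. Of 20 members, all tested, 9 were lower and 0 higher, and 14 were lower when adjusted over the list alone. The median log2 fold change was -1.21 (camera adjusted p = 6.49e-05), a call that was lost with an estimated correlation (adjusted p = 0.813) and under fry (adjusted p = 0.175). Besides Idi1, the 4 genes with the smallest p included Hmgcs1 (-1.21, SE 0.23), Dhcr7 (-1.41, SE 0.30) and Nsdhl (-1.59, SE 0.34). The size of the fall depended on sham 3, which stood above sham 1 and 2 by a median log2 difference of 1.20. The median difference of the tumour libraries was -1.87 from sham 3 and -0.55 from sham 1 and 2. Nsdhl, for example, had 32.8 to 34.3 CPM in the tumour libraries, 69.9 and 70.9 in sham 1 and 2, and 163 in sham 3.

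Cell cycle genes changed in both directions. Of 20 members 5 rose and 5 fell (8 and 6 when adjusted over the list alone; camera adjusted p = 0.543). The cyclin genes Ccnb2 (1.16, SE 0.18) and Ccna2 (0.69, SE 0.11) rose, and the replication helicase genes Mcm2 (-0.80, SE 0.08) and Mcm3 (-0.55, SE 0.09) fell. Named after their values were seen, Mki67 (0.89), Birc5 (0.70) and Tpx2 (0.84) rose as well, and Mcm5 (-0.83), Mcm6 (-0.61) and Tyms (-0.65) fell. Of 18 immediate early and heat shock genes 3 rose, Hspb1, Hspa1a (0.94) and Hspa1b (0.92), the last pair being near-identical copies (camera adjusted p = 0.0674, the same counts when adjusted over the list alone). This list separated sham 3 from the other sham libraries, with a median log2 difference of -1.98. It was called higher in the tumour libraries without sham 1 (camera adjusted p = 0.00832) and without sham 2 (0.00486), but without sham 3 its median was -0.22 (camera adjusted p = 0.126).

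Markers of other cell types gave few calls, and some were abundant in both groups. Named after their values were seen, the collagen gene Col1a2 had 2330 ± 16.7 CPM in the tumour and 2650 ± 1010 CPM in the sham libraries, Cldn11 858 ± 17.6 and 826 ± 213 CPM, Cdh5 575 ± 2 and 560 ± 54.4 CPM, and Cnp 113 ± 3.36 and 119 ± 8.34 CPM. Which cells these transcripts came from was not analysed here. Of 11 tested microglia and macrophage markers 2 rose, among them the lysosomal gene Cd68, from 7.54 ± 2.57 to 44.0 ± 2.35 CPM (camera adjusted p = 0.263), while Cx3cr1, P2ry12 and Csf1r stayed below 1 CPM in every library. Of the leukocyte list 3 of 20 genes were expressed enough to test and 0 were called (camera adjusted p = 0.764). The pair with the highest levels was Plac8, at 30.4 ± 1.14 and 12 ± 13.2 CPM (4.4, 4.41 and 27.3 CPM in sham 1 to 3; log2 fold change 2.78 and called without sham 3), and Lck, at 1.01 and 0.721 CPM. Among 12 neuronal genes Gad1 rose (1.70, at 6.33 CPM; 0.97, adjusted p = 0.0766, with transcript length offsets) and Syn1 fell (-1.89, at 0.709 CPM), with a camera adjusted p of 0.802. Aspa fell among 9 oligodendrocyte genes (0.802), Pdgfra rose (0.63, from 167 ± 34.2 to 258 ± 6.06 CPM) among 7 oligodendrocyte precursor genes (0.802), Kdr fell (-1.29, SE 0.15) among 9 endothelial genes (0.802), and Col3a1 fell (-1.03, SE 0.14, from 1190 ± 205 to 585 ± 16 CPM) among 12 mural and fibroblast genes (0.973), where the values in parentheses after each list are camera adjusted p. Pdgfra was the 1 precursor gene with a positive log2 fold change, while 6 had a negative value and the list had a median of -0.33. Among 10 ependymal and choroid plexus genes 0 were called (camera adjusted p = 0.973). Their pair with the highest levels was Foxj1, at 93.1 ± 0.953 and 122 ± 37.4 CPM, and Rarres2, at 20 ± 2.12 and 8.16 ± 4.18 CPM. Without sham 3 Foxj1 was called lower (-0.63) and Rarres2 higher (0.94), the latter also without sham 2 (1.67) and by DESeq2. Over that list sham 3 was below sham 1 and 2 by a median log2 difference of -1.51, and over the neuronal list it was above them by 0.75. For these 8 lists the counts were unchanged when adjusted over the list alone.

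Markers of the tumour cells themselves gave 1 call. Of 24 neuroendocrine and epithelial genes 10 could be tested, of which 1 rose and 0 fell (1 and 2 when adjusted over the list alone; camera adjusted p = 0.543), and 9 of the 10 had a negative log2 fold change. The median log2 difference of the tumour libraries was -0.48 from sham 1 and 2 and 0.40 from sham 3. The one that rose was the keratin gene Krt19, from 2.23 ± 1.72 to 21.1 ± 0.219 CPM (log2 fold change 3.25, SE 0.47, edgeR adjusted p = 0.00656; 4.08 without sham 3). Epcam had 0.331, 0.329 and 0.237 CPM in the tumour libraries and 0 reads in each sham library, which allows up to 0.136 CPM (3 reads, counting error only). Chga, the gene of chromogranin A, had 0 reads in each tumour library, which allows up to 0.124 CPM by the same count.

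**Figure D4:**
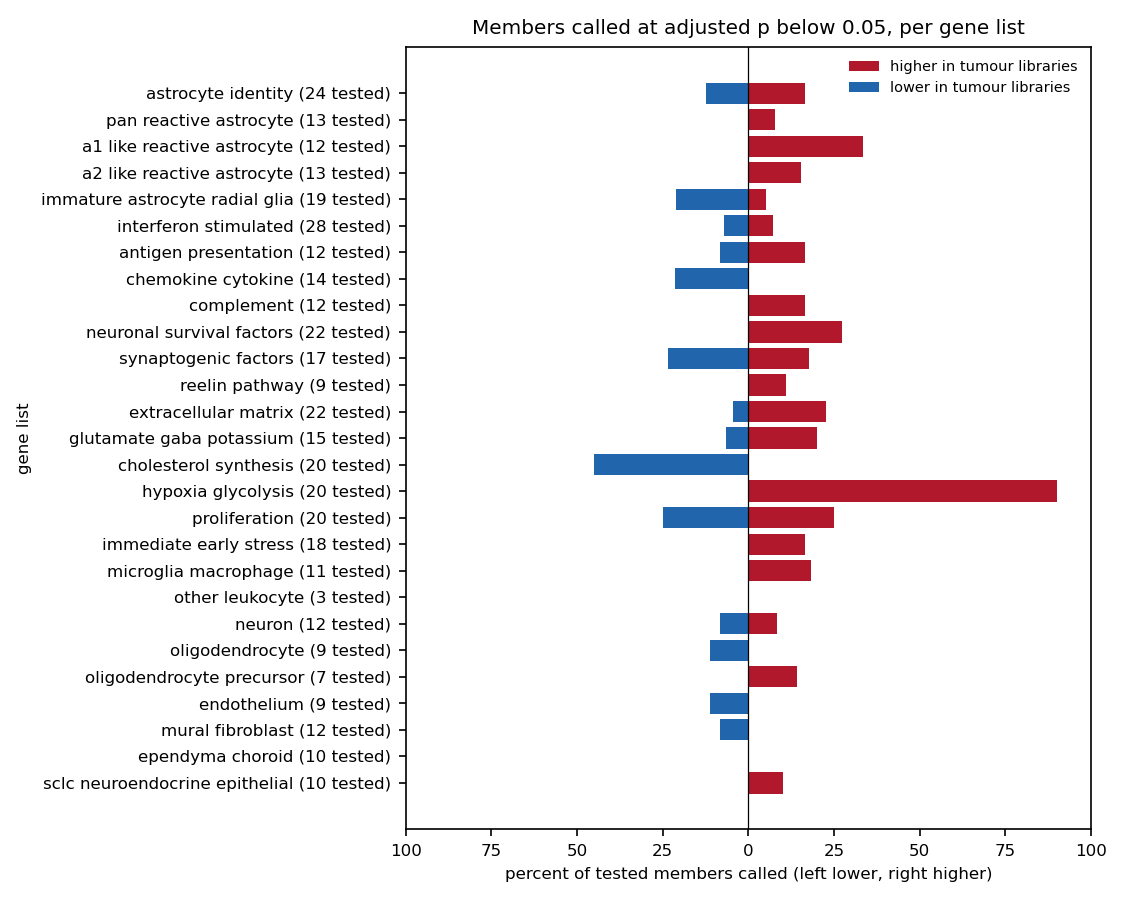
Percent of the tested members of each of the 27 gene lists that were called higher (right, red) or lower (left, blue) in the tumour libraries by edgeR at an adjusted p below 0.05; the number tested stands beside each name. Hypoxia and glycolysis (18 of 20 higher) and cholesterol synthesis (9 of 20 lower) have the longest bars.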

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

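The number of calls moved with the setting. The sums of near libraries were chosen after seeing the data; the other alternatives were fixed before. The counts of 1506 higher and 1492 lower genes stayed within 1.5 times under DESeq2 (1878 and 1830), DESeq2 size factors, upper quartile factors, either filter and limma-voom. They did not with transcript length offsets (1075 and 969, the first within 1.5 times), limma-voom with sample quality weights (4150 and 4066), glmTreat against a log2 fold change of 1 (76 and 7) or the sums of near libraries, where edgeR and limma-voom each called 0 and 0 (538 and 688 genes at an unadjusted p below 0.05) and DESeq2 called 78 and 10. Leaving out 1 library gave 536 to 4250 higher and 355 to 4179 lower genes, most without sham 3. Without sham 3 the sham group kept only sham 1 and 2, whose common biological coefficient of variation was 0.04, against 0.263 over sham 1 to 3. The cause of these moves was not tested further. With the replicate number as a block, 829 genes were higher and 607 lower. Same-numbered libraries did not deviate together (correlations across genes of 0.008, -0.019 and -0.001). Because the tumour libraries almost coincided, these correlations could hardly show a pairing and decide nothing. The main fit had no block because the labels do not say that same-numbered libraries share an animal or a day.

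Of 97 named genes with a fold change, 81 were called, and none of them changed sign in any of the 19 alternatives. Since the groups were apart in each called gene, leaving out or summing libraries could hardly turn a sign. Among the genes not called, 21 comparisons had the opposite sign, and C3 ranged from -0.59 to 0.62. Leaving out 1 library ended the call of 39 of the 81; on the sums, where the tumour group has 1 value and no spread of its own, DESeq2 called 24 of the 81 and edgeR and limma-voom 0. Of 2 lists higher and 1 lower, camera with an estimated correlation left 1 and 0. Fry called 4 higher and 1 lower, the chemokine list (adjusted p = 0.0328), and not the cholesterol list (0.175). Camera without a filter called 5 higher, and leaving out 1 library 2 to 5 higher and 1 to 3 lower. The hypoxia list was called in each of its 12 alternatives (median 1.71 to 1.77, adjusted p 3.96e-23 to 0.0165). The mature astrocyte list turned to -0.25 without sham 3 (adjusted p = 0.0466; median up to 0.19, without sham 2, and adjusted p up to 0.972 over its alternatives), and fry called synaptogenic factors higher although their median was -0.13 (adjusted p = 0.0328; 0.0328 to 0.992 over its alternatives); the cause was not tested. Depth limits statements on Reln, Epcam and other genes under 1 CPM.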

Other observations

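All tests on sham 3 and on the near libraries, the test of tumour cell markers and that of a shared preparation were chosen only after the result was seen, as were the genes named here for sham 3. The other predictions were written before their values were computed, but after the patterns they concern had been seen. Sham library 3 differed from the other sham libraries in several gene groups that the comparison of tumour with sham averages out. Immediate early genes, which respond within minutes to stimulation or tissue handling, were far lower in it. Fos had 166 CPM in sham 3 against 1540 and 1610 in sham 1 and 2 and 1250 to 1270 in the tumour libraries. Fosb had 38.4 CPM against 1210 and 1110, and Atf3 1.18 CPM against 84.0 and 88.2. C3, a complement gene of reactive astrocytes, had 33.4 CPM against 172 and 181. In the other direction, Vcan (versican), the chromatin protein gene Hmga2 and the matrix protease gene Mmp3 stood at 548, 217 and 314 CPM in sham 3, at 77.3, 36.9 and 22.9 CPM in sham 1, and at 317, 215 and 127 CPM in tumour library 1. These are values of single libraries and carry no test.

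Of 383 genes at least 2-fold higher in sham 3 than in sham 1 and 2, 206 were also at least 2-fold higher in the tumour libraries, but both differences contain sham 1 and 2, so an overlap arises without any likeness and decides nothing. A tumour library under a sham label would carry the hypoxia genes if the tumour itself raised them. Their median log2 difference from sham 1 and 2 was -0.10, against 1.71 for the tumour libraries. If conditions of a single preparation raised them, a tumour library of another preparation would lack the rise, so these values cannot settle the label. A lower share of astrocytes was predicted to raise the markers of each other cell type. The ependymal and choroid plexus list instead had a median of -1.51 with 9 of 10 members below 0. Medians were also below 0 for microglia and macrophages (-0.58), endothelium (-0.19) and oligodendrocytes (-0.18). They were above 0 for neurons (0.75), oligodendrocyte precursors (0.50) and mural cells and fibroblasts (0.45), while mature astrocyte genes had -0.79. Fewer astrocytes need not raise every other cell type, so this explanation stays open. Lower depth is argued against by its total, 1.004 times that of sham 1. A separate preparation, animal or handling may lie behind it and stays open, and no biological explanation was tested since the labels put all 3 in one group.

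A candidate explanation for the closeness of tumour libraries 1 to 3, and of sham 1 and 2, is that each set holds repeat libraries of one preparation. Sampling noise gives a chi-square per gene that does not grow with depth, whereas differences between animals do. Genes were put into classes by their reads in the pair. Expected counts followed the library totals in classes below 500 reads, and the median share of the class from 500 reads up. Values of the lower and upper classes are therefore not strictly comparable. From the class with the fewest reads to that with the second most, the chi-square per gene changed by a factor of 0.87 to 0.98 in the 4 near pairs. Between sham 3 and sham 1 or 2 that factor was at least 3.86. The class with the most reads was left out of these factors. The common biological coefficient of variation was 0.043 within the tumour libraries and 0.040 between sham 1 and 2, against 0.263 over all 3 sham libraries. In the class with the most reads the near pairs differed more, with 3.24 to 5.27 per gene against 2.72 to 3.08 in the class with the fewest. The chi-square per gene thus did grow there, and every class lay above the 1 per gene that sampling noise alone gives. Genetically alike animals processed together also remain possible, so whether the near libraries are repeats stays open.

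Tumour cells in the preparation could raise the hypoxia and glycolysis genes, and would also raise the neuroendocrine and epithelial markers fixed beforehand, whose median log2 fold change was -0.33 with 9 of 10 tested members below 0. They stay open, because that median was -0.48 against sham 1 and 2 but 0.40 against sham 3, several markers such as Scg3 (241 CPM) were as high in the sham libraries, and Krt19 (log2 fold change 3.25, and 4.08 without sham 3) and Epcam (0.237 to 0.331 CPM against 0 reads) went the other way. GC content, transcript length or expression level would move other genes alike, but the highest median among 10000 lists matched on all 3 was 0.41, against 1.71. Conditions of one preparation, such as low oxygen during isolation or growth of the tumour samples, may produce the same rise and cannot be told apart from an effect of the tumour, since the labels do not say how many preparations the tumour libraries came from and their closeness (0.98 by the measure above) does not settle it. The biological explanation, exposure of astrocytes to the tumour, stays open as well.

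A hypothesis beyond the fixed lists is that the ATF4 response to amino acid shortage was active in the tumour libraries, prompted by Trib3 (3.77), Chac1 (2.85) and Mthfd2 (1.78), which had been seen to rise. In a list of 24 genes of that response written after those were seen, 17 rose and 0 fell. Without the 3 prompting genes, 14 of 21 rose and 0 fell, with a median log2 fold change of 0.78 (camera p = 1.87e-08, and p = 0.0186 with an estimated correlation), as the hypothesis requires. The list cannot show whether a shortage of amino acids or something else raised these genes. Conditions of a single tumour preparation cannot be told apart here either. With the preset correlation camera also called lists in each other split of the libraries, as given below. A first run had left out 4 further genes by mistake and gave a median of 0.73 over 17 genes, so the run over 21 was made with that value known. Stc2 (2.90), the cystine transporter gene Slc7a11 (1.56) and the cationic amino acid transporter gene Slc7a1 (1.33) rose, whereas the serine synthesis genes Phgdh (-0.29, adjusted p = 0.135) and Psat1 (-0.05, adjusted p = 0.631) were not called. A general endoplasmic reticulum stress response may contribute, because 16 chaperone and degradation genes of that compartment had a median of 0.33 with 5 higher and 0 lower (camera p = 0.000666, but p = 0.089 with an estimated correlation). The median of the 21 ATF4 genes was 0.88 against sham 1 and 2 and 0.52 against sham 3. That of the 16 chaperone and degradation genes was 0.4 and only 0.11. Calls in both lists are to be read beside the 20.9% of all tested genes that were called.

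The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split called 2998 genes and the highest of the others called 0, so 1 split gave as many. Each other split puts nearly coinciding tumour libraries into both groups, which by itself widens the spread within groups. The 0 calls there therefore say nothing about chance. For gene lists the real split called 3, whereas the highest of the others called 9 and all 10 splits gave at least as many as the real one. Counts of 5 to 9 against 3 may point to a structure of the samples, though no test separates this from calls made too freely under the preset correlation.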
